A study of Homo sapiens with 6 samples.

How the data were processed

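Gene expression was measured in 6 samples of HUF-1 skin fibroblasts, 3 sorted as SSEA3-high and 3 as SSEA3-negative, on the Affymetrix U133 plus 2.0 array, which carries several probe sets for many genes. Per the labels' protocols, cells were stained with an SSEA3 antibody, sorted by a gate fixed on the top and bottom 10% of cells, plated for 24 h, and 100 ng of total RNA was amplified by a NuGEN kit, which can distort levels and 5' to 3' signal. Per the labels the replicates of a group are biological, and nothing states whether they came from separate sorts, so p-values measure the spread between these samples of 1 line. Description fields of the samples that speak of embryos were not used, since the other fields describe human skin cells.

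The deposited table holds intensity values on a linear scale, 1 column per array, for 54675 probe sets. The software that summarised the probes is not given in the sources used here. In each array the mean after trimming 2% at each end was 500.1, so the deposited intensities had been scaled to a common level by the authors, which fixes the average of an array and leaves differences in the shape of its distribution. No detection calls were used here, so dim values were not separated from background by a test. The number of arrays limits the precision.

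From these values log2(intensity + 16) was computed after raising values below 1 to 1, which applied to 1299 values (0.396%). A log2 difference on this scale understates the change of dim genes. Array medians on this scale differed by at most 0.079, under the limit of 0.1 set in advance, so no further normalization was applied in the main test. The 62 Affymetrix control probe sets were left out of the tests, which leaves 54613. Of these, 41091 had 1 gene, 1801 several and 11721 none named here. Gene symbols were updated through gene identifiers to a RefSeq gene table of assembly GRCh38.p14, used for names only, where 41037 of the probe sets matched and 54 kept the older symbol. No coordinates are given, since no build is given in the sources used here. Each of 19775 genes was represented by its probe set of highest mean over all 6 arrays, and that probe set was kept in every alternative that retained it.

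Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5, and figures drawn with Python 3.11.15 and matplotlib 3.10.9. The groups were compared by lmFit and eBayes without an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all probe sets or over all genes at a threshold of 0.05. The 25 gene lists were tested together by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. They were globo-series glycolipid synthesis, ganglioside synthesis and glycolipid breakdown, pluripotency, mesenchymal stromal surface markers, dermal papilla and neural crest, fibrillar collagen and matrix, matrix proteases and inhibitors, contractile genes, inflammatory cytokines and chemokines, interferon response, wound and growth factors, cell cycle, senescence and p53 targets, immediate early and stress genes, hypoxia and glycolysis, cholesterol synthesis, TGF-beta and BMP response, Wnt and Notch, HOX genes, and markers of keratinocytes, melanocytes and Schwann cells, endothelium, pericytes, leukocytes and adipocytes. List medians were also set against 10000 random lists of genes with like mean expression. Single array measures were compared by exact permutation tests, for which 3 against 3 gives a smallest two-sided p of 0.1.

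The groups, main tests, lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took genes that passed without overlap; since 0 passed, it took the 10 largest positive and 10 largest negative differences among the 100 smallest p-values, up to 4 members of each list by smallest p, and B3GALT5, B3GALNT1, A4GALT, POU5F1, NANOG, SOX2, NT5E, ENG and THY1. From the lists the text names the members of smallest p. XIST and Y-linked genes were left out. The alternatives fixed in advance were quantile normalization, median centring, a replicate block, an intensity trend with robust prior, array weights, removal of the dimmer probe sets, removal of cross-hybridising probe sets, a log2 difference of at least 1, pseudocounts of 1 and 64, the mean of a gene's probe sets, other set tests and leaving out each array. Probe sets counted here as cross-hybridising were those whose names end in _s_at, _x_at or _a_at, and 37394 were left without them. That is a rule by name, which does not show that a given probe set cross-hybridises. Cyclic loess normalization, the actin ratio as covariate, and the alternatives run on the intensity trend test were chosen after seeing the data.

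The tests were run on simulated data of 19775 genes with the spread of this comparison. Values were drawn independently from normal distributions, and the changed genes were all brighter than the median probe set, so the shares recovered do not cover dim genes. Of 50 genes changed by a log2 of 1, limma without a trend recovered 50% and with a trend and robust prior 66%; for a log2 of 0.5 the shares were 0% and 34%, and for a log2 of 2 they were 90% and 94%. Among the unchanged genes each model made 3 false calls. Camera called the 1 shifted list and 0 of 24 unshifted ones. The simulation held no correlation between genes and no brightness difference between groups, so it does not show how camera behaves where these are present.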

Results

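Messenger RNA levels were measured in HUF-1 cells, a line of primary fibroblasts from adult human skin, on Affymetrix U133 plus 2.0 arrays. The cells had been sorted by flow cytometry on SSEA3, stage-specific embryonic antigen 3, a globo-series glycolipid of the cell surface best known from pluripotent stem cells. The SSEA3-high group came from the 10% of cells with the strongest stain and the SSEA3-negative group from the 10% with the weakest. Both were left to adhere for 24 h before RNA was purified, and each group held 3 biological replicates, which limits the precision of every value. The median intensity of an array was 57.8 ± 1.17 in SSEA3-high and 58.3 ± 2.10 in SSEA3-negative cells (SD, n = 3). Over all probe sets the correlation was 0.966 to 0.969 within SSEA3-high and 0.972 to 0.973 within SSEA3-negative arrays. Between the groups it was 0.965 to 0.971, so SSEA3-high arrays were no more alike than arrays of different groups. The actin 5'/3' signal ratio, a measure of RNA integrity and amplification, was 0.551 ± 0.191 in SSEA3-high and 0.853 ± 0.037 in SSEA3-negative arrays, with no overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). That of GAPDH was 1.02 ± 0.032 against 1.07 ± 0.012, also without overlap (exact permutation p = 0.1).

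The comparison of the 2 populations asks how skin cells with much surface SSEA3 differ in expression from cells with little. ST3GAL5, the sialyltransferase that makes the ganglioside GM3 from lactosylceramide, had an intensity of 340.3 ± 23.4 in SSEA3-high and 712 ± 29.0 in SSEA3-negative cells, a log2 difference of -1.03 ± 0.12 (SE). FST, a secreted antagonist of activin, was at 2794 ± 199.5 against 5080.4 ± 187 (log2 difference -0.86 ± 0.12), with all 3 of its probe sets lower. TNFRSF11B, the decoy receptor osteoprotegerin, was at 2246 ± 468 against 1054 ± 28.4 (1.06 ± 0.17). ACKR3, a scavenging receptor of the chemokine CXCL12, was at 1452 ± 182 against 717 ± 21.2 (1.00 ± 0.14; 0.43 as the mean of its probe sets), and the sarcomeric actin gene ACTC1 had a log2 difference of 0.75 ± 0.12. TNFRSF11B, ACKR3 and ACTC1 were chosen after their values were seen.

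In limma's test without an intensity trend, 0 of 54613 probe sets and 0 of 19775 genes passed an adjusted p of 0.05. The smallest adjusted p of a gene was 0.192. At an unadjusted p under 0.05 there were 1497 genes, 783 higher and 714 lower in SSEA3-high cells, where chance gives 989, and 4377 probe sets, where chance gives 2731. The values of the groups did not overlap for 3651 genes, or 18.5%, where chance gives 10%. With an intensity trend and robust prior, limma called 291 genes, 235 higher and 56 lower, among them FST (adjusted p = 0.0014), ACTC1 (0.00079), ACKR3 (0.0043), ST3GAL5 (0.0045) and TNFRSF11B (0.0045). Of the 235 higher genes, 170 had a mean log2 value above 13, as did 4.08% of all genes.

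That count of 291 moved with scaling and with single arrays. It was 76 (46 higher, 30 lower) after quantile normalization and 79 (47 higher, 32 lower) after cyclic loess normalization. It was 26, 166 and 357 without SSEA3-high replicates 1, 2 and 3, and 19, 27 and 29 without SSEA3-negative replicates 1, 2 and 3. With each array's actin 5'/3' ratio as a covariate it was 2. That ratio did not overlap between the groups, so it partly stands for the group itself. The drop therefore cannot tell whether the 5' signal lay behind the calls. A set of 68 genes, 41 higher and 27 lower, was called under the deposited, quantile and loess scaling alike. Of these, 15 were called with each array left out in turn, which was run on the deposited scaling only. The lower ones were ST3GAL5, FST and VAT1L (-1.03 ± 0.15). The higher ones were TNFRSF11B, HSPB7 (1.01 ± 0.13; 0.54 as the mean of its probe sets), ACKR3, COL10A1 (0.90 ± 0.11), GRAMD2B (0.87 ± 0.13), STC1, ACTC1, CRYAB (0.64 ± 0.13; 0.41 after quantile normalization), CXCL6, ANPEP, ENPP2 (0.55 ± 0.11) and LTBP2. VAT1L, HSPB7, COL10A1, GRAMD2B, CRYAB and ENPP2 were chosen after their values were seen.

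**Figure D1:**
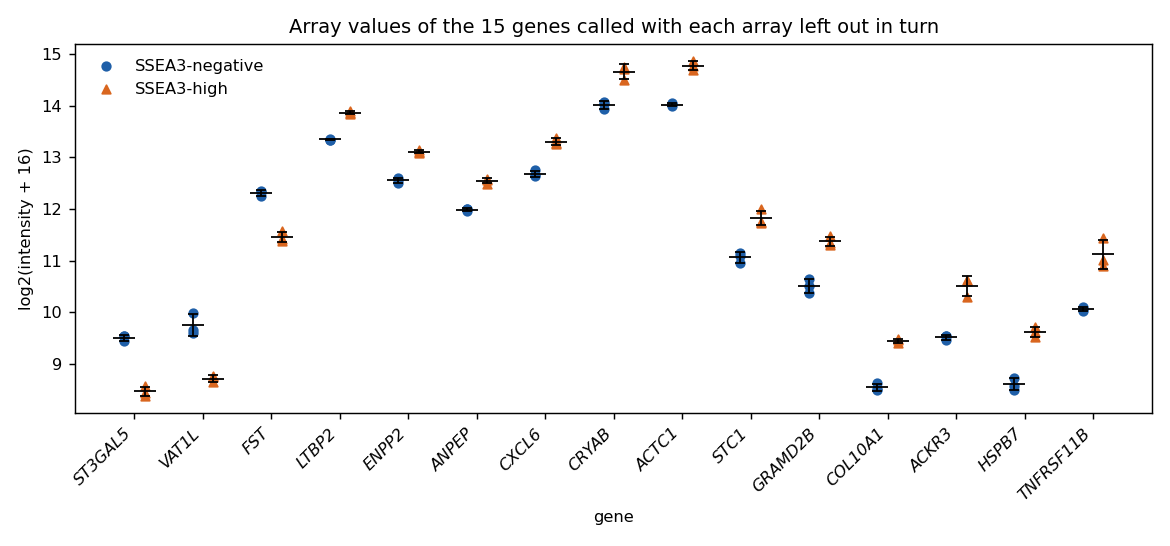
Log2(intensity + 16) of the 15 genes on each array, SSEA3-negative as circles and SSEA3-high as triangles, with black bars at the mean ± SD of 3 arrays. The groups do not overlap for any of the 15 genes, of which 3 were lower and 12 higher in SSEA3-high cells. The genes were selected by their calls on these same arrays, so this separation is no further evidence.

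Because SSEA3 is a glycolipid, the enzymes that make it were examined by name. B3GALT5, the galactosyltransferase that completes the SSEA3 epitope, had an intensity of 38.8 ± 26 in SSEA3-high and 43.2 ± 17.8 in SSEA3-negative cells, below the array median (log2 difference -0.16 ± 0.39; 0.50 as the mean of its 3 probe sets). The other 2 were higher, 1 of them at 48.7 against 14.6 (log2 difference 1.21 ± 0.49, limma's unadjusted p = 0.0487). B3GALNT1, which makes globoside, the step before it, differed by -0.16 ± 0.12 (-0.10 after quantile normalization). All 3 of its probe sets were lower, 1 of them by -0.35 ± 0.11 (limma's unadjusted p = 0.0219). A4GALT, the Gb3 synthase, differed by 0.24 ± 0.30. Without SSEA3-high replicates 1, 2 and 3 B3GALT5 was at 0.06, -0.01 and -0.52, and without the SSEA3-negative ones at -0.44, 0.0013 and -0.04. A4GALT was at 0.10 and 0.44 without SSEA3-high replicates 2 and 3, and at -0.01 and 0.44 without SSEA3-negative replicates 2 and 3. Among the 8 members of the globo-series list, 5 were higher and 3 lower, 0 of them at an unadjusted p under 0.05, and the list did not pass limma's camera (adjusted p = 0.635). B4GALT6 (0.36 ± 0.23), B4GALT5 (0.13 ± 0.11) and GBGT1 (0.21 ± 0.21) did not pass either, and 0 members passed adjusted over the list alone. With the mean of probe sets B4GALT6 differed by 0.10 and B4GALT5 by 0.21, and without SSEA3-high replicates 1 and 2 B4GALT6 differed by 0.14 and 0.56. GBGT1 was at 0.09 without SSEA3-high replicate 1, and at 0.31 and 0.03 without SSEA3-negative replicates 1 and 2. In the list of ganglioside synthesis and glycolipid breakdown, 8 of 12 measured members were lower. Without the intensity trend ST3GAL5 and B3GNT5 (-0.99 ± 0.19), which starts the lacto-series, passed adjusted over the list alone, while 0 members passed over all genes. With the trend and robust prior limma called ST3GAL5 over all genes (adjusted p = 0.0045, and 0.0029 after quantile normalization) but not B3GNT5 (adjusted p = 0.0727). NEU1, a lysosomal sialidase, differed by -0.45 ± 0.18 and HEXA by -0.29 ± 0.12. Camera did not call the list (adjusted p = 0.174), and fry did (adjusted p = 0.022). ST3GAL5 has 1 probe set here, whose name ends in _s_at, so it had no value without cross-hybridising probe sets. Without them camera gave the list an adjusted p of 0.998. Of the 3 probe sets of B3GNT5 and the 4 of HEXA, 2 and 3 were higher. The mean of probe sets gave -0.10 for B3GNT5 and 0.19 for HEXA.

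Pluripotency genes were mostly dim in both populations. NANOG had an intensity of 6.52 ± 4.95 in SSEA3-high and 12.7 ± 13.5 in SSEA3-negative cells, and SOX2 70.5 ± 8.34 and 54.8 ± 26.8. Of 19 measured members, 10 were higher and 9 lower, and 2 had a mean log2 value of 8 or more, an intensity of about 240.0. The brightest, PODXL, the sialomucin podocalyxin, was at 13389 ± 266 against 10431 ± 1092, a log2 difference of 0.36 ± 0.13 with an adjusted p of 0.63 (0.22 after quantile normalization). ESRRB (0.98 ± 0.42), TERT (0.86 ± 0.44) and KLF17 (-0.89 ± 0.47) had mean intensities under 68. The mean of probe sets gave 0.24 for ESRRB, 0.52 for TERT, 0.03 for SOX2 and -0.02 for NANOG. Without SSEA3-high replicate 1 TERT was at 0.55, KLF17 at -0.59 and NANOG at -0.45, without replicate 2 KLF17 was at -1.44 and NANOG at -0.18, and without replicate 3 ESRRB was at 0.55. Without SSEA3-negative replicate 1 NANOG turned to 0.08 and SOX2 was at 0.07, and without replicate 2 they were at -0.53 and 0.63. Camera did not call the list (adjusted p = 0.635), and 0 members passed adjusted over the list alone without the intensity trend. With the trend and robust prior limma called PODXL over all genes (adjusted p = 0.0402), though not after quantile normalization (adjusted p = 0.239). POU5F1 had no probe set of its own on this array and was not analysed here.

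Surface markers of mesenchymal stromal cells rose as a list (camera adjusted p = 0.0388; adjusted p = 0.412 with an estimated correlation), with 13 of 17 members higher and 4 lower. ANPEP, the aminopeptidase CD13, was at 5979 ± 208 against 4045 ± 67.2 (log2 difference 0.56 ± 0.11). ALCAM (0.46 ± 0.12) and BST1 (0.60 ± 0.15) were higher and the adhesion molecule VCAM1 (-0.62 ± 0.15) lower. Adjusted over the list alone without the intensity trend, 5 members were higher and 2 lower, and 0 passed over all genes. With the trend and robust prior limma called 4 members over all genes, all higher, among them ANPEP (adjusted p = 0.0049) and ALCAM (0.0089). After quantile normalization it called 2. The classical markers NT5E (0.24 ± 0.16), ENG (0.14 ± 0.14) and THY1 (0.10 ± 0.11) did not pass (adjusted p = 0.743, 0.845 and 0.861), and the mean of all probe sets turned ENG to -0.19 and THY1 to -0.15 and gave 0.10 for NT5E. NT5E was at 0.15 without SSEA3-high replicate 3 and 0.14 without SSEA3-negative replicate 1, and ENG at 0.08 and 0.05 without replicate 1 of each group. ANPEP differed by 0.25 without cross-hybridising probe sets and 0.26 with the mean of probe sets, and ALCAM by 0.26 after quantile normalization and 0.25 with that mean. The list's adjusted p was 0.34 after quantile normalization, 0.174 after cyclic loess, 0.147 without cross-hybridising probe sets, 0.656 with the mean of probe sets, 0.243 without SSEA3-high replicate 2, 0.0654 without SSEA3-high replicate 3, and 0.15 and 0.111 without SSEA3-negative replicates 1 and 3.

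In the deposited values most genes of the extracellular matrix lists were higher on the SSEA3-high arrays, as were bright probe sets as a whole. In the list of fibrillar collagen and matrix genes 34 of 37 members were higher, with a median log2 difference of 0.26, and the list rose (camera adjusted p = 2.04e-09; adjusted p = 0.285 with an estimated correlation). Tenascin C, TNC, was at 25259.7 ± 878 against 18455 ± 608 (log2 difference 0.45 ± 0.11). COL1A1 (0.46 ± 0.12), COL12A1 (0.46 ± 0.12) and FBN2 (0.59 ± 0.17) were also higher. The list of matrix proteases and inhibitors rose too, with 24 of 27 members higher and a median of 0.24 (camera adjusted p = 8.02e-06; adjusted p = 0.312 with an estimated correlation). It held MMP14 (0.40 ± 0.12), a membrane collagenase, SERPINE2 (0.41 ± 0.11), TIMP3 (0.38 ± 0.12) and TIMP1 (0.40 ± 0.14). At an unadjusted p under 0.05 the matrix list had 16 members higher and 1 lower and the protease list 8 higher and 0 lower. Without the intensity trend 0 passed in both over all genes and 0 adjusted over the list alone. With the trend and robust prior limma called 12 matrix and 7 protease members over all genes, all higher, and 0 of either after quantile normalization. After quantile normalization the list medians were 0.06 and 0.11 (adjusted p = 0.0399 and 0.0407), TNC differed by 0.20, COL1A1 by 0.06, SERPINE2 by 0.15, TIMP3 by 0.11 and TIMP1 by -0.0042. With the mean of each gene's probe sets the protease list had an adjusted p of 0.132, COL1A1 differed by 0.15, COL12A1 by 0.03, FBN2 by 0.39, MMP14 by 0.20, SERPINE2 by -0.013 and TIMP3 by -0.0063.

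The bright end as a whole was higher on the SSEA3-high arrays. Probe sets with a mean log2 value from 9 to 10 had a median difference of -0.04, those from 13 to 14 of 0.14 and those from 15 to 17 of 0.40. The 99th percentile of intensity was 17710.1 ± 549 in SSEA3-high and 15456 ± 585 in SSEA3-negative arrays, although the trimmed mean of each array was 500.1. These were also the arrays of lower actin 5'/3' ratio. The bacterial hybridisation controls, which come from no cell, were higher as well, 17 of 18 without overlap. The bioB controls, with a mean log2 near 10, were higher by a median of 0.28 and the brighter cre and bioD controls by 0.49. Several of these probe sets read the same transcript (bioB, bioC, bioD or cre), so they are not independent. The median of the matrix list was above 99.97% of 10000 random lists of genes of like brightness, and above 98.7% after quantile normalization. For the proteases these values were 99.8% and 99.7%, for TGF-beta and BMP 99.9% and 95.2%, for mesenchymal markers 85.9% and 98.1% and for hypoxia and glycolysis 84.8% and 22.3%.

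**Figure D2:**
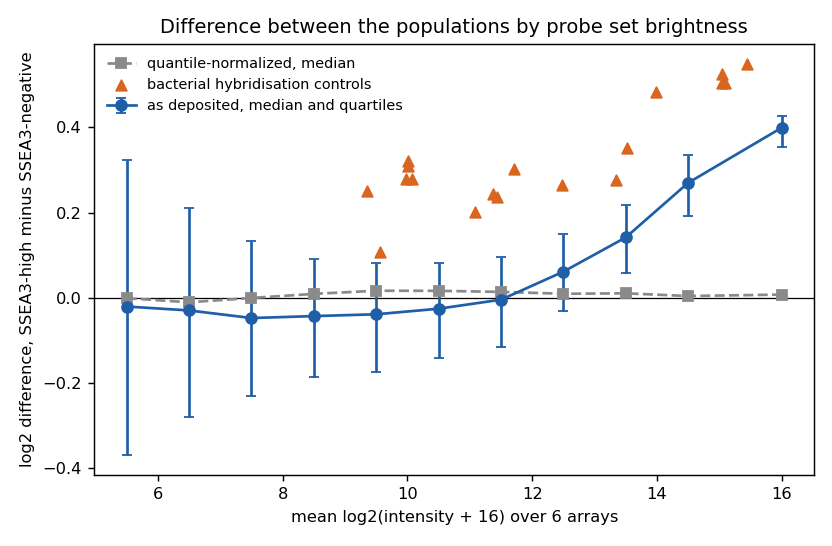
Log2 difference between SSEA3-high and SSEA3-negative arrays (means of 3) against the mean log2(intensity + 16) of a probe set, as medians with quartiles per bin (circles) and as medians after quantile normalization (squares), with bacterial hybridisation controls as triangles. As deposited, the median climbs from -0.04 at 9 to 10 to 0.40 at 15 to 17, and the controls lie between 0.11 and 0.55.

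**Figure D3:**
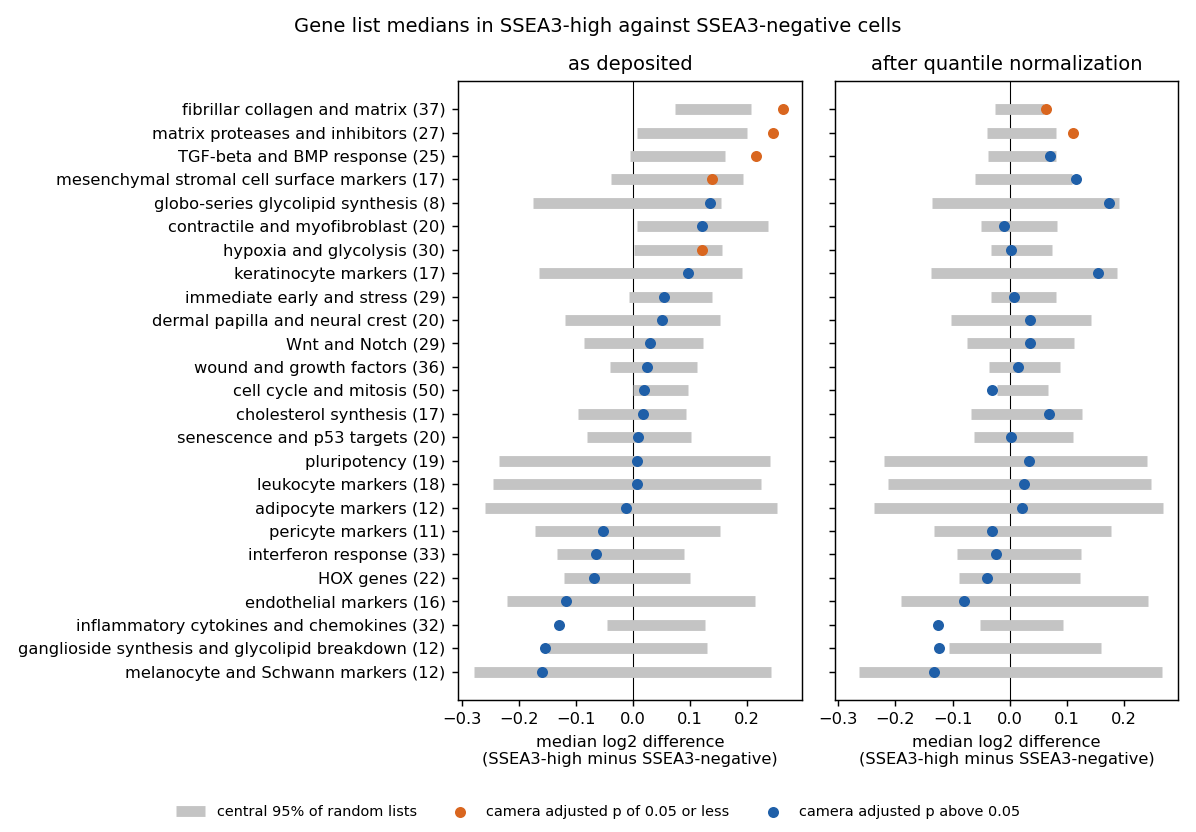
Median log2 difference (SSEA3-high minus SSEA3-negative) of the 25 gene lists, measured members in brackets, as deposited and after quantile normalization, with grey bars for the central 95% of 10000 random lists of like brightness. Camera called 5 lists as deposited and 2 after quantile normalization (orange points).

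Genes of TGF-beta and BMP signalling rose as a list, 19 of 25 members higher and 6 lower (camera adjusted p = 0.0056; adjusted p = 0.364 with an estimated correlation). LTBP2, a microfibril protein of the matrix, was at 14851 ± 292 against 10383 ± 95.6 (log2 difference 0.52 ± 0.11). PMEPA1 (0.60 ± 0.15) and ID1 (0.37 ± 0.12; 0.04 after quantile normalization), both targets of the pathway, were higher, and the antagonist FST was the member with the smallest p and was lower. Adjusted over the list alone without the intensity trend, 1 member was higher and 1 lower. With the trend and robust prior limma called 5 higher and 1 lower over all genes, and 2 and 1 after quantile normalization. Hypoxia and glycolysis genes rose as a list, 21 of 30 higher (camera adjusted p = 0.0296, and 0.499 with an estimated correlation). Without the intensity trend 0 members passed adjusted over the list alone. The list had 4 members, all higher, that limma called over all genes with the trend and robust prior, and 0 after quantile normalization. Its LDHA (0.46 ± 0.14), GAPDH (0.38 ± 0.12) and PGAM1 (0.35 ± 0.12) are bright glycolytic genes that differed by 0.06, -0.0028 and 0.09 after quantile normalization, and VLDLR (0.42 ± 0.15) by 0.48. After quantile normalization the adjusted p of the lists was 0.34 for TGF-beta and BMP and 0.752 for hypoxia and glycolysis, after cyclic loess 0.174 and 0.507, and without cross-hybridising probe sets 0.0719 and 0.96. For hypoxia it was 0.3004 with the mean of probe sets and 0.0828 with fry. It was 0.0634 for both without SSEA3-high replicate 2, 0.0652 and 0.15 without SSEA3-negative replicate 1, and for hypoxia 0.156 without SSEA3-high replicate 1 and 0.0635 without SSEA3-negative replicate 3.

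Secreted growth factors went both ways. PTN (-0.91 ± 0.15) and MDK (-0.81 ± 0.15), the related heparin-binding factors pleiotrophin and midkine, were lower in SSEA3-high cells, while STC1 (0.76 ± 0.14), a secreted glycoprotein, and the EGF receptor ligand TGFA (0.80 ± 0.16) were higher. Adjusted over the list of wound and growth factors alone without the intensity trend, 2 members were higher and 2 lower, and 0 passed over all genes. Of its 36 members 19 were higher (camera adjusted p = 0.635). With the trend and robust prior limma called 4 higher and 2 lower members over all genes, and 2 and 2 after quantile normalization. PTN, MDK, STC1 and TGFA were called under both scalings. Of the 4 probe sets of PTN 3 were lower, and it differed by 0.22 without cross-hybridising probe sets. The mean of probe sets gave -0.51 for PTN, 0.48 for STC1 and 0.21 for TGFA. Among inflammatory cytokines and chemokines 19 of 32 members were lower (camera adjusted p = 0.219). The neutrophil chemokine CXCL6 was at 10102 ± 430.2 against 6575 ± 263 (0.62 ± 0.11), the NF-kB feedback inhibitor TNFAIP3 was at 2034 ± 246 against 3043 ± 67.9 (-0.58 ± 0.14), and CCL8 (-1.11 ± 0.23) and CXCL10 (-0.96 ± 0.21) were dim. Adjusted over the list alone without the trend, 1 was higher and 5 lower. With the trend and robust prior limma called 3 higher and 2 lower inflammatory members over all genes, and 1 and 2 after quantile normalization. Interferon response genes, led by ISG15 (-0.30 ± 0.11) and IFIT2 (-0.49 ± 0.18), were lower in 18 of 33 cases (adjusted p = 0.278), with 0 adjusted over the list alone and -0.32 for IFIT2 as the mean of probe sets.

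Contractile genes were split. ACTA2, smooth muscle actin, was at 7706 ± 415 against 10212 ± 501 (log2 difference -0.41 ± 0.12), with 3 of 3 probe sets lower and -0.23 as their mean. The bright genes CCN2 (0.46 ± 0.13), CCN1 (0.40 ± 0.12) and TPM1 (0.41 ± 0.13) were higher, by 0.07, 0.03 and 0.0028 after quantile normalization, and TPM1 by 0.06 without cross-hybridising probe sets. The list had a mean of -0.0054 and a median of 0.12, which quantile normalization turned to -0.01, and an adjusted p of 0.445. In the Wnt and Notch list WNT5A (-0.46 ± 0.12) was lower in both of its probe sets (-0.72 without cross-hybridising probe sets), and NKD2 (1.00 ± 0.27), SFRP2 (0.63 ± 0.19) and DKK1 (0.40 ± 0.12; 0.08 after quantile normalization) were higher (adjusted p = 0.58). In the dermal papilla and neural crest list the transcription factor TFAP2A (-0.97 ± 0.18) was lower, and VCAN (0.52 ± 0.12), the proteoglycan versican, and SOX9 (0.38 ± 0.12) were higher, with -0.28 for TFAP2A and 0.21 for VCAN as the mean of probe sets. Adjusted over that list alone 1 member was higher and 1 lower (adjusted p of the list 0.652). In the contractile and the Wnt and Notch lists 0 members passed adjusted over the list alone. These list counts are without the intensity trend. With the trend and robust prior limma called, over all genes, 4 contractile members higher and 1 lower. It called 1 higher and 1 lower in Wnt and Notch, and 1 higher and 0 lower in the dermal papilla list. After quantile normalization the counts were 0 and 1, 0 and 1, and 1 and 0.

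Lists of proliferation, stress and position did not pass. Of 50 cell cycle genes 27 were higher and 23 lower (adjusted p = 0.748), with RRM2 at 0.34 ± 0.12 and TK1 at -0.29 ± 0.13, and after quantile normalization RRM2 differed by 0.12. The list median of 0.02 became -0.03 after the same step. Senescence and p53 targets (adjusted p = 0.841) were led by ZMAT3 (-0.76 ± 0.32) and SESN1 (-0.26 ± 0.12), with a mean of -0.03 and a median of 0.0081. Immediate early and stress genes (adjusted p = 0.445) held NR4A1 (0.93 ± 0.26), HMOX1 (0.40 ± 0.11) and ATF3 (-0.40 ± 0.15). Cholesterol synthesis genes (adjusted p = 0.437) held INSIG1 (0.41 ± 0.12) and STARD4 (0.38 ± 0.12). HOX genes (adjusted p = 0.367) were lower in 14 of 22 cases, with HOXC11 (-0.81 ± 0.40) and HOXA2 (0.68 ± 0.38) dim. HOXC11 was at -0.48 without SSEA3-high replicate 1 and -1.24 without replicate 2, HOXA2 at 0.43 without SSEA3-high replicate 2 and 0.39 without SSEA3-negative replicate 2, and ZMAT3 at -0.49 without SSEA3-high replicate 1. Without cross-hybridising probe sets NR4A1 turned to -0.25 and ATF3 differed by -0.0079. HMOX1 differed by 0.24 after quantile normalization, and the mean of probe sets gave 0.42 for NR4A1, -0.24 for ATF3, -0.28 for ZMAT3, 0.22 for RRM2 and 0.19 for INSIG1. In these 5 lists 0 members passed adjusted over the list alone without the intensity trend. With the trend and robust prior limma called over all genes 4 immediate early and stress genes, 1 cell cycle gene and 1 cholesterol synthesis gene, all higher. After quantile normalization these counts were 0, 0 and 1.

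Markers of other cells that a skin culture can hold did not separate the populations as lists, and most were dim. Keratinocyte markers (adjusted p = 0.437) had 5 of 17 members at a mean log2 of 8 or more. ITGB4 (1.18 ± 0.30) was higher, KRT14 (-1.08 ± 0.30) lower, and both were under an intensity of 148. Melanocyte and Schwann markers (0 of 12 at that level, adjusted p = 0.557) were led by PMEL (-1.07 ± 0.46) and MITF (0.32 ± 0.14), and endothelial markers (1 of 16, adjusted p = 0.684) by KDR (0.46 ± 0.20) and ESAM (0.57 ± 0.28). Pericyte markers (6 of 11, adjusted p = 0.39; 3 members also in another list) were led by NOTCH3 (-0.37 ± 0.12) and MCAM (-0.19 ± 0.11). Leukocyte markers (0 of 18, adjusted p = 0.635) were led by CD74 (1.17 ± 0.27) and CD163 (1.08 ± 0.43), and adipocyte markers (0 of 12, adjusted p = 0.652) by CD36 (-0.69 ± 0.23) and FABP4 (-1.05 ± 0.38). ITGB4 (-0.33), CD163 (-0.15) and MCAM (0.0045) turned direction without cross-hybridising probe sets, and MITF (-0.17) with the mean of probe sets. That mean gave 0.23 for CD74, 0.60 for CD163, -0.19 for CD36, 0.14 for ITGB4 and -0.09 for MCAM. Without SSEA3-high replicates 1 and 2 ESAM was at 0.37 and 0.86, and without SSEA3-negative replicate 2 KDR was at 0.26. In these 6 lists 0 members passed adjusted over the list alone.

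The largest log2 differences among the 100 smallest p-values, of which 41 were higher and 59 lower, belonged to dim genes that did not pass. The higher ones were DLGAP4-AS1 (1.84 ± 0.32), EPS8L3 (1.78 ± 0.27), RHEX (1.75 ± 0.25), CXCL17 (1.73 ± 0.26), MAJIN (1.66 ± 0.19), OR52D1 (1.51 ± 0.15), CPVL (1.35 ± 0.13), GUCA2A (1.34 ± 0.14), LINC01616 (1.33 ± 0.23) and ADAMTS16 (1.23 ± 0.20). The lower ones were COX17 (-1.86 ± 0.30), FAM167B (-1.65 ± 0.31), INHBB (-1.56 ± 0.26), CD70 (-1.50 ± 0.29), SLC19A3 (-1.48 ± 0.12), LOC339260 (-1.47 ± 0.28), ZNF235 (-1.39 ± 0.13), FCRL5 (-1.38 ± 0.13), PCDHGB6 (-1.37 ± 0.26) and LINC02579 (-1.36 ± 0.17). Their adjusted p ran from 0.192 to 0.415, and FCRL5 turned to 0.12 without cross-hybridising probe sets. The mean of probe sets gave 0.78 for RHEX, -0.81 for SLC19A3 and -0.38 for FCRL5. With a pseudocount of 64 in place of 16 all 20 were smaller by over 1.5 times, from 0.50 (ADAMTS16) to 0.88 (CXCL17) and from -0.58 (LINC02579) to -0.93 (COX17). The highest group mean among them was 97.8 ± 20.9, that of INHBB, which encodes an activin subunit, in SSEA3-negative cells, against 23.0 ± 10.7 in SSEA3-high cells.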

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

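The test of the hybridisation controls was chosen after the result was seen. Bright probe sets were higher in SSEA3-high arrays, and so were controls that come from no cell. The cre and bioD controls, added at hybridisation, differed by a median log2 of 0.49 (8 of 8 without overlap). The poly-A controls, bacterial transcripts that are usually added to the RNA, differed by 0.68 (11 of 24 without overlap, range -0.24 to 0.91). In both sets several probe sets read the same transcript, so these counts are not of independent measures. Among the poly-A probe sets named r2-Bs, dap differed by 0.81 at the 3' end and -0.07 at the 5' end, and thr by 0.86 and -0.13. For phe the values were 0.82 and 0.46, and for lys 0.82 and 0.75. So in some transcripts from no cell the 5' signal was also lower relative to the 3' signal. An array-wide difference in brightness is a candidate explanation for the bright genes. However, the bioB controls, with a median of 0.28 at a mean log2 near 10, were also above probe sets of like brightness. So were these 3' poly-A probe sets, which makes the poly-A controls no plain measure of brightness. The hypoxia and glycolysis list, at the 22.3 percentile of random lists of like brightness after quantile normalization, went with brightness. The matrix and protease lists, at the 98.7 and 99.7 percentiles, lay above the central 95% of such lists. The random lists were drawn as unrelated genes, while the matrix and protease lists had estimated correlations of 0.054 and 0.060. The band may thus be too narrow, so whether brightness was their whole source is not settled. The lower actin 5'/3' ratio and a difference between the sorted populations also stay open, and neither list passed with an estimated correlation.

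ST3GAL5 was lower in SSEA3-high cells, with a log2 difference of -1.03 ± 0.12. Its only probe set is counted by name as cross-hybridising, so the removal of such probe sets left no value for this gene. After quantile normalization the difference was -0.98 (95% interval -1.26 to -0.71). That step could move the gene little, whatever the cause. Probe sets with a mean log2 value from 8 to 9, where ST3GAL5 lies (8.99), had a median difference of -0.04 before it and 0.01 after. It is this small difference among probe sets of like brightness (quartiles -0.19 and 0.09 as deposited) that argues against the brightness of the arrays. SSEA3-high replicate 3, whose actin 5'/3' ratio of 0.761 was nearest to the SSEA3-negative arrays, lay -19.1 SD from their mean, but this is 1 array against an SD of 3, so the 5' signal stays open, although the GAPDH 5'/3' ratio (1.02 against 1.07) differed less than that of actin. With the actin ratio as a covariate the difference was -1.09 ± 0.20, with an adjusted p of 0.166 under the intensity trend, where the wider error ended the call. A difference between the populations also stays open and was not tested on other cells.

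The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. Without a trend all 10 splits gave 0 genes and all 10 gave 0 probe sets. With the trend and robust prior the real split gave 291 genes and the highest of the others 0, so 1 of 10 reached the real count. For lists the real split gave 5 and the highest other 1, and for genes at an unadjusted p under 0.05 the real split gave 1497 and the highest other 909, again 1 of 10 in both cases.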

How the results depend on the processing

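Cyclic loess, the actin covariate and each alternative run on the intensity trend test were chosen after seeing the data. The counts of 0 probe sets and 0 genes stayed at 0 under every alternative run except the intensity trend with robust prior (373 probe sets, 270 higher and 103 lower; 291 genes), where the pooled variance depends on brightness; a replicate block gave 0 genes and 0 probe sets. The 5 lists became 2 with quantile or cyclic loess normalization, with cross-hybridising probe sets removed or with the mean of all probe sets, 3 with a replicate block (adjusted p = 0.0755 for both the mesenchymal and the hypoxia list), 0 with an estimated correlation, and 2 to 5 with 1 array left out. The 291 genes became 76 with quantile and 79 with cyclic loess normalization, 69 without the robust prior and 60 with a replicate block. They became 2 with the actin covariate, which costs a degree of freedom and did not overlap between the groups. With 1 array left out they became 19 to 357. Replicate numbers did not pair the arrays (same-number correlations of 0.0014, 0.0063 and 0.0061), although each array correlated best with its own number, a hint from the data only. Of 116 named genes 17 reversed under some alternative. Without cross-hybridising probe sets another probe set stood for the gene, and the value was -0.15 for CD163, 0.12 for FCRL5, 0.13 for HEXA, -0.33 for ITGB4, 0.0045 for MCAM, -0.25 for NR4A1 and 0.22 for PTN. The mean of all probe sets gave 0.50 for B3GALT5, -0.19 for ENG, 0.19 for HEXA, -0.17 for MITF, -0.013 for SERPINE2, -0.15 for THY1 and -0.0063 for TIMP3. Quantile normalization gave -0.0028 for GAPDH and -0.0042 for TIMP1. With 1 array left out A4GALT ran from -0.013 to 0.44, B3GALT5 from -0.52 to 0.056 and NANOG from -0.53 to 0.085, all dim. The cause of the other moves was not tested. Of 1791 gene values in all 1724 kept direction and side of the threshold and 47 newly passed it, all under the intensity trend. Since 0 genes had passed in the main test, no call could be lost. A kept value could also shrink, as TPM1 did from 0.41 to 0.0028 after quantile normalization. Of 471 list values 440 kept their side of the threshold, 30 no longer passed and 1 newly passed (fry). The median turned sign in 42 of the 471, all in lists that had not passed. Signal over background limits the dim genes, but it was not measured here. A pseudocount of 64 shrank 39 and one of 1 enlarged 30 of the named differences by over 1.5 times. An added constant does this to differences between dim values, whatever their background.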

Other observations

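The use of the globo-series list as a test beside ST3GAL5 was chosen after the result was seen. Of the 68 genes called under all 3 scalings with the intensity trend, 41 were higher and 27 lower. The 4 given here are among the lower ones, were chosen after their values were seen and stand for no group. KRT18, a keratin of simple epithelia, differed by -0.79 ± 0.13, the transcription factors FOXC2 by -0.74 ± 0.14 and SOX11 by -0.68 ± 0.14, and NFKBIA, the NF-kB inhibitor, by -0.72 ± 0.17 (limma adjusted p = 0.005, 0.0089, 0.0157 and 0.0181 with the trend). On the deposited scaling FOXC2 was called with 3 of 6 single arrays left out, KRT18 with 5, and SOX11 and NFKBIA with 2. The inflammatory list, which holds NFKBIA and TNFAIP3, had a median of -0.13, above 0.02% of random lists of like brightness, although camera did not call it.

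Whether less GM3 synthase left more lactosylceramide for the globo series was not tested here. The globo-series list did not pass (camera adjusted p = 0.635, 5 of 8 members higher), but freed substrate would need no change in these transcripts, so the list decides nothing. The lipids and the enzyme activity were not analysed here.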
